A study of Mus musculus with 4 samples.

How the data were processed

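Gene expression was measured in mouse liver on 4 Affymetrix arrays, 1 for each treatment group. Per the labels and the series design, RNA of the 3 mice of groups P+P and E+P and of the 5 mice of groups P+E and E+E was pooled by group before labelled cRNA was made. The deposited values were intensities: linear probe set signals for 45101 probe sets per array, with none missing and none negative. The software that summarised the probes, its version and its scaling method were not given in the sources used here. The values themselves showed a scaling by the authors, because the mean left after removing the lowest and highest 2% of probe sets was 499.8 on every array. The median signals still differed, at 129.9 (P+P), 134.1 (E+P), 153.1 (P+E) and 152.0 (E+E).

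Groups were taken from the sample titles. The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a later choice is stated. Quantile normalization had been set as the step to take where the medians of the log2 signals of the arrays lay more than 0.1 apart, and they lay 0.24 apart. The deposited intensities were therefore quantile-normalized over the 4 arrays and expressed as log2(signal + 43.2), where 43.2 was the 25th percentile of all deposited signals. Ratios are differences on this scale, which understates differences of genes with low signals. Quantile normalization also fixes the value at each rank, so ratios of the most abundant transcripts are compressed. Log2 ratios of genes with a signal near background on either array depend on the pseudocount. A fold against a signal below the filter level is given as at least the fold against that level, a choice made after the data were seen. Differences of ratios of named genes were given with such signals set to that level as well, and so were some log2 ratios.

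Probe sets were named through the platform annotation of the array, with symbols updated through Entrez identifiers in a RefSeq gene table (assembly GRCm38.p6), which was used for names only. Of the probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none listed, and 64 were controls. A symbol was found through the Entrez identifier for 34741 probe sets. No coordinates are given, since no genome build was named for the array. Each of the 18193 genes was represented by its probe set with the highest mean signal. The low-level filter kept genes whose mean reached the median of all probe sets (a signal of about 120.0), which left 11513 genes. Probe sets of closely related genes can share signal. This holds for the serum amyloid A, metallothionein, orosomucoid and cytochrome P450 genes, and their values are uncertain to that extent.

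With 1 array per group no p-value or standard error was computed. A model with additive effects of the exposures would leave 1 residual degree of freedom and take the difference of ratios as noise, and it was not run. A difference of at least 2-fold (1 on the log2 scale) was used as a fixed rule of size, and it describes 2 arrays, not the treatments in general. The second-exposure ratios were P+E against P+P and E+E against E+P, which share no array. The first-exposure ratios were E+P against P+P and E+E against P+E, which share no array either. Other pairs of ratios do share an array, so their chance errors go together. Shared genes were set beside the overlap of independent lists, over all genes and, as added after the data were seen, within 20 bins of signal. The difference of the 2 second-exposure ratios described whether the first exposure altered the response to the second. It also holds the error of every array and cannot be told from it.

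For 37 gene lists (24 pathways and 13 cell types), the median log2 ratio of the members past the filter was set beside 10000 random lists of the same size matched on signal in 20 bins. A median below the 2.5th or above the 97.5th percentile of the random lists was called apart. This is a description of these arrays and not a p-value. Members of the lists that had no probe set of their own were not analysed here. The lists overlap, with up to 5 shared measured genes between any 2 of them. Lists for a second set of pancreatic acinar genes, pancreatic endocrine genes, clock genes of the opposite phase and skeletal muscle genes were added after the data were seen.

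The named genes were chosen as follows. For the second exposure they were the 12 highest and 12 lowest by the mean of both ratios among genes at least 2-fold the same way in both. For the first exposure they were the 6 highest and 6 lowest among genes at least 1.5-fold the same way in both. The 5 highest and 5 lowest of each single ratio and the 6 highest and 6 lowest differences of ratios were added. So were up to 4 members of each list with the largest ratios and 16 genes of drug metabolism and stress fixed beforehand, of which Gsta1 was not analysed here. Clone and predicted names were left out.

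The steps were tested on simulated arrays made from the observed levels and noise, with known differences planted. The noise came from the difference of the second-exposure ratios, so it also holds any true difference between them. For P+E against P+P, run on 11538 genes, 96.3% and 97.0% of genes planted at a log2 ratio of -1.5 and 1.5 passed the 2-fold rule, and 100.0% at 2.0 or 3.0 in either direction. Noise alone put 705 of 11374 unchanged genes at least 2-fold apart in that simulated comparison, and 67 of them the same way in both second-exposure ratios. Of 200 random unchanged lists, 10 were called apart. The simulated noise was independent between genes, so this share follows from the percentile cuts. Genes of a real list can vary together, and the rate of false calls for such lists was not measured.

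Control probe sets and agreement between probe sets of a gene served as quality checks. Precision was limited by the number of arrays. The alternatives covered 2 other pseudocounts, 2 other scalings, 2 other treatments of multiple probe sets, no low-level filter and a stricter one. The E+P array in place of the P+P array as control was added after the data were seen, because the 18S rRNA control probe sets of P+P stood apart. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.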

Results

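Liver gene expression was measured in 2-month-old C57BL/6J mice that received ethylbenzene, an aromatic solvent, or phosphate-buffered saline (PBS) in a first and again in a second exposure. The first exposure was 2 intraperitoneal injections 24 h apart. The second followed after 7 days, and livers were taken 5 h later. Each ethylbenzene dose was 7 mmol per kg. The groups are named by the first and then the second exposure: P+P and E+P (3 mice each), P+E and E+E (5 mice each). The RNA of each group was pooled and measured on 1 array, so there were no replicates and no difference could be tested against the spread between animals. Pool size followed the second exposure and cannot be separated from it. The P+P array differed from the others in its control probe sets. The geometric mean signal of 3 probe sets for 18S ribosomal RNA was 1872 on P+P, 122 on E+P, 145 on P+E and 182 on E+E, and that of the Actb control probe sets was 8928, 22081, 24573 and 30540. The ratio of the 3' to the 5' control signal, in the same order, was 23.51, 7.21, 6.15 and 12.03 for Pcx, 4.55, 3.84, 3.48 and 3.77 for Actb and 1.06, 0.91, 0.94 and 0.97 for Gapdh. The geometric mean signal of 18 hybridisation spike probe sets was 9868, 10252, 11971 and 15057, highest on E+E.

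The second exposure was compared in mice given PBS first (P+E against P+P) and in mice given ethylbenzene first (E+E against E+P). Pairs of values below are in this order. Acute phase genes, whose products the liver secretes in inflammation, were higher on both ethylbenzene arrays. Lcn2, which encodes an iron-sequestering protein, was at least 361-fold and 123-fold higher (its P+P signal of 96.8 lay below the filter level of 120.0, which was used in its place), and Saa2, a serum amyloid A gene, 149-fold and 177-fold higher. Cyp2b10, a cytochrome P450 gene typically induced through the receptor CAR, was 197-fold and 58.4-fold higher, with all 3 of its probe sets in that direction. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 41.4-fold and 30.5-fold lower. Dbp, a transcription factor driven by the circadian clock, was 10.8-fold and 28.8-fold lower.

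Of 26 acute phase genes, 12 were at least 2-fold higher in both ratios and none was at least 2-fold lower in both. Their median log2 ratio was 1.26 and 0.90, each at percentile 100 of random lists. Saa1 (5.75 and 6.12), Orm2 (4.41 and 2.76) and Socs3 (4.03 and 3.56), a feedback inhibitor of cytokine signalling, were among them. The chemokine gene Cxcl1 was higher by 5.30 and 5.29. The NF-kB and chemokine list as a whole (13 genes) had medians of 0.21 (percentile 94.3, but 97.9 at a common 75th percentile) and 0.58 (percentile 99.8). Markers of neutrophils moved with these genes only in part. The list of 6 had medians of 1.06 (percentile 100) and 0.91 (percentile 99.7), but 2 of the 6 were at least 2-fold higher in both ratios and 1 was at least 2-fold lower in the first. S100a9 was higher by 3.62 and 4.83 (4.31 with E+P at the filter level), while Ngp was at -0.89 and 1.33.

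**Figure D1:**
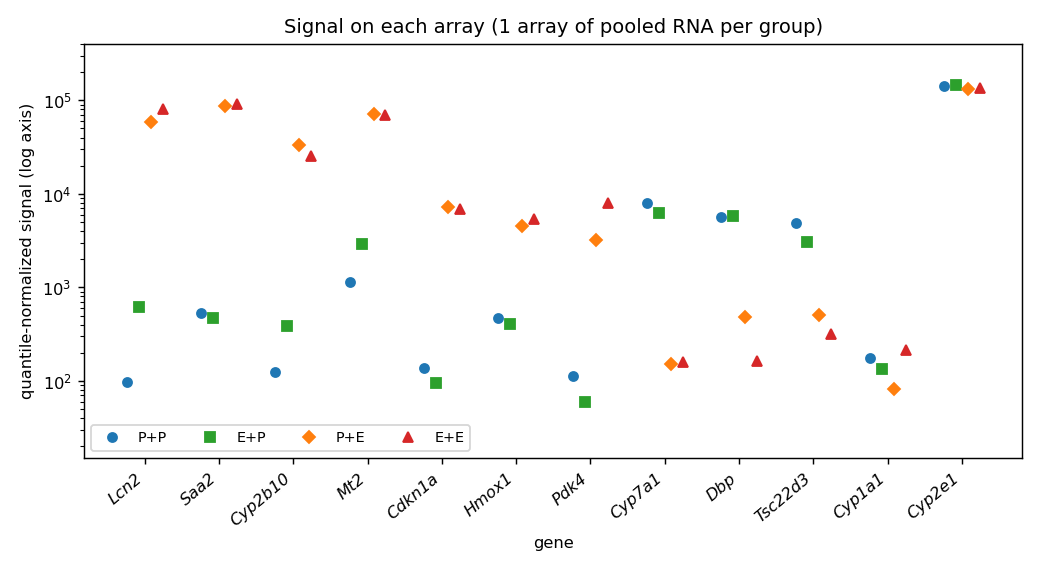
Quantile-normalized signal (log axis) of 12 genes on the 4 arrays, where each point is 1 array of pooled RNA. Lcn2 stood at 96.8 on P+P and 620 on E+P against 58918 on P+E and 81707 on E+E, while the signals of Cyp2e1 lay between 132377 and 144274 and the sign of its ratios depended on the scaling.

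In the list of 29 CAR/PXR drug metabolism genes, 5 were at least 2-fold higher in each ratio, 3 of them in both. The median was 0.25 (percentile 100) and 0.04 (percentile 96.6). The second value lay within the random lists here but above them as deposited (0.13, percentile 99.6) and at a common 75th percentile (0.09, percentile 99.4). Beside Cyp2b10, Gadd45b, a stress-inducible gene, was higher by 3.62 and 3.66 and Cyp3a13 by 1.81 and 1.12. Cyp2c55 was at 0.83 and 0.54, and Cyp3a11, an abundant cytochrome P450 gene, at 0.10 and 0.04. Cyp2e1, whose product oxidizes small solvents, was at -0.09 and -0.10, but at 0.16 and 0.23 as deposited. Of 5 targets of the aryl hydrocarbon receptor (AHR), only Tiparp was at least 2-fold apart in either ratio (3.04 and 3.49). Cyp1a1 was at -0.83 (-0.44 with its low signal at the filter level) and 0.54, Cyp1a2 at -0.41 and -0.57, and the list medians were -0.41 (percentile 6.0) and 0.18 (percentile 84.5).

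The NRF2 and glutathione list (36 genes) had medians of 0.14 (percentile 99.4) and 0.21 (percentile 99.9), although the first was 0.07 and no longer apart when the probe sets of each gene were averaged. Hmox1, which degrades heme, was 8.87-fold and 12.2-fold higher and was the only member at least 2-fold higher in both, while Akr1c19 was lower (-1.53 and -1.26). The classical NRF2 targets Nqo1 (-0.21 and 0.18) and Gclc (-0.49 and -0.49) were not higher in both. Of 7 metallothionein and metal genes, 4 were higher in both: Mt2 (5.94 and 4.58), Mt1 (4.91 and 3.50), and the metal transporter genes Slc39a14 (1.98 and 2.53) and Slc30a10 (2.44 and 1.88). The iron uptake receptor gene Tfrc was lower by both ratios (-1.5 and -1.4). The list medians were 1.98 and 1.88, both at percentile 100.

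Early stress genes were higher as well. Of 22 immediate early genes, 11 were at least 2-fold higher in both ratios, with medians of 1.06 and 1.22 (percentile 100 each), among them Junb (3.27 and 3.04) and Egr1 (3.06 and 2.98). The p53 and DNA damage genes split. Of 16, 7 were at least 2-fold higher in both, and the medians were 0.17 (percentile 93.7, within the random lists) and 0.84 (percentile 100). In the first ratio 9 were above 0 and 7 below, and in the second 11 and 5. Mdm2 of this list was at 0.22 and 0.96, short of 2-fold. Cdkn1a, a cell cycle inhibitor, was 40.6-fold and at least 42.1-fold higher, and Gadd45a was higher by 4.10 and 3.29. The 16 cell cycle genes had medians of -0.02 (percentile 62.5) and -0.04 (percentile 47.1), with Ccnd1 at -1.59 in both ratios.

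The 23 glucocorticoid targets split. Their medians were 0.64 and 0.71 (percentile 100 each), and 9 were at least 2-fold higher in both ratios, including Lcn2, Mt1, Mt2, Cdkn1a and Igfbp1 (4.89 and 4.0), an insulin-like growth factor binding protein gene. Tsc22d3 (-3.16 and -3.10), among the typical glucocorticoid-induced genes, and Per1 (-1.66 and -2.82, the latter -1.64 with E+E at the filter level) were lower in both. The list shares 4 measured genes with the gluconeogenesis and amino acid catabolism list and 2 with the metallothionein list. It shares 1 each with the acute phase, clock, immediate early, p53, periportal and hepatocyte lists.

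The lists of sterol and fatty acid synthesis had medians below the random lists, although few members were at least 2-fold lower in both ratios (1 of 19 and 3 of 21). The 19 sterol synthesis genes had medians of -0.45 and -0.85 (percentile 0.0 each), with 1 and 7 at least 2-fold lower, and with Idi1 at -0.95 and -1.77 and Insig1 at -0.93 and -1.61. The 21 fatty acid synthesis genes had medians of -0.34 (percentile 0.4) and -0.37 (percentile 0.1), whereas Pnpla3 of that list was higher (2.25 and 1.74). The signals of Pnpla3 on P+P and E+P lay below the filter level. With these set to that level, it was 2.46-fold higher in the first ratio, and its second log2 ratio was 0.99, short of 2-fold. Among 21 bile acid genes, 2 were at least 2-fold lower in both, Cyp7a1 and Cyp7b1 (-1.91 and -1.46), and the medians of 0.02 (percentile 85.5) and -0.27 (percentile 3.2) lay within the random lists, but the second was below them as deposited (-0.29, percentile 2.1) and at a common 75th percentile (-0.33, percentile 2.1). Angptl8, an insulin-responsive secreted factor, was 18.7-fold and 7.11-fold lower. The PPARα and fatty acid oxidation list (31 genes) was not apart (medians 0.04, percentile 91.8, and -0.07, percentile 63.7). Pdk4, which restrains glucose oxidation, was at least 20-fold and at least 48.6-fold higher, and Plin2, a lipid droplet coat protein, higher by 1.88 and 1.78. The gluconeogenesis and amino acid catabolism list (17 genes) had medians of -0.02 (percentile 75) and -0.18 (percentile 20.7).

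Of 17 circadian clock genes, 7 were at least 2-fold lower and 2 at least 2-fold higher in both ratios, with medians of -0.90 and -0.98 (percentile 0.0 each). Beside Dbp, the lower genes included Usp2 (-3.89 and -3.80) and Ciart (-2.15 and -3.96, the latter -2.56 with E+E at the filter level). The higher ones were Arntl (1.99 and 1.75) and Nfil3 (1.81 and 2.01). Some genes of the exocrine pancreas were also higher on both ethylbenzene arrays. Of 9 pancreatic acinar markers, 8 were at least 2-fold higher in both ratios, with medians of 2.58 and 2.26 (percentile 100 each). Ctrb1, a chymotrypsinogen gene, had signals of 10.8 on P+P, 12.9 on E+P, 785 on P+E and 804 on E+E, and Cela3b, an elastase gene, 132, 21.4, 2052 and 1903. In a second acinar list added after the data were seen, 5 of 16 measured genes were at least 2-fold higher in both. Carry-over of pancreatic tissue is taken up under the other observations.

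By count, 752 genes were at least 2-fold higher and 771 lower on P+E than on P+P, and 796 higher and 777 lower on E+E than on E+P. In both ratios, which share no array, 330 were higher and 214 lower, where independent lists of these sizes would share 52.0 in each direction, or 58.1 and 67.4 when matched on signal. Opposite ways went 53 genes, against 122.1 for matched lists. Across the 11513 genes, which are not independent replicates, the ratios correlated with a Pearson r of 0.50 and a Spearman rho of 0.40, and with 0.86 and 0.68 among the 3838 most abundant. Other genes among the highest by both ratios were Fbf1 (4.16 and 5.28), Arid5a (4.32 and 4.68) and Tacc2 (4.34 and 4.64), and among the lowest Paqr7 (-3.54 and -3.77), Nrep (-3.96 and -2.77), Hhex (-2.73 and -3.46) and Syde2 (-2.77 and -3.20). With low signals set to the filter level, Arid5a was at 3.58 and 3.87, Paqr7 at -2.39 and -2.61 and Syde2 at -1.67 and -1.84. Mcm10 (-3.65 and -3.27) was lower too, but only 1 of 2 probe sets past the filter had that direction in the first ratio. The counts depended on the low-level filter: at the 75th percentile they were 355 higher and 264 lower in the first ratio and 380 and 290 in the second.

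**Figure D2:**
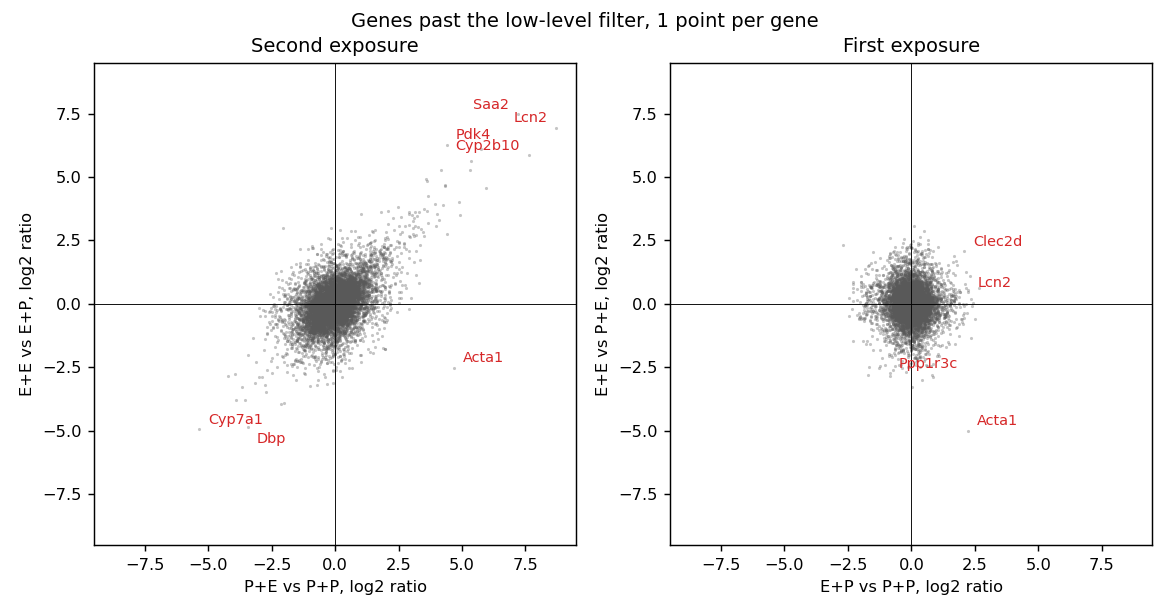
Log2 ratios of the 11513 genes past the low-level filter, 1 point per gene, with the second-exposure ratios against each other on the left and the first-exposure ratios on the right. The second-exposure ratios correlated with r of 0.50 and the first-exposure ratios with r of -0.02.

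The first exposure was compared 7 days later in mice given PBS second (E+P against P+P) and in mice given ethylbenzene second (E+E against P+E), and pairs of values are in this order from here. Few genes differed the same way in both ratios. Acute phase genes leaned higher: 21 of 26 were above 0 in each ratio, with medians of 0.27 (percentile 100) and 0.10 (percentile 99.8), and Lcn2 was at 2.24 (at least 2.02 with P+P at the filter level) and 0.47. Saa1 (-0.39 and -0.02) and Saa2 (-0.18 and 0.07), among the highest genes of the second exposure, were not higher in both. Markers of Kupffer cells, the resident macrophages of the liver, also leaned higher, with 12 and 11 of 13 above 0 and medians of 0.57 (percentile 100) and 0.19 (percentile 98.5). The complement gene C1qa was at 0.94 and 0.03 and Cd5l at 0.67 and 0.40.

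Of the other lists, none was apart the same way in both ratios. The interferon response list (0.15, percentile 97.4, and 0.21, percentile 97.7) and the male-predominant list (-0.37, percentile 0.0, and -0.14, percentile 2.7) came close. Among the 34 lists with at least 3 genes past the filter, 9 were apart in the first ratio (3 above and 6 below) and 10 in the second (6 above and 4 below). At such rates lists can be apart the same way in both by chance. ER stress and integrated stress genes (29) had medians of -0.33 (percentile 0.0) and 0.26 (percentile 100), and neutrophil markers -0.58 (percentile 0.9) and 0.63 (percentile 98.7). Sterol synthesis genes were at -0.09 (percentile 12.4) and -0.35 (percentile 0.0), fatty acid synthesis genes at 0.02 (percentile 60.5) and -0.22 (percentile 0.0), and gluconeogenesis genes at -0.05 (percentile 18.4) and -0.31 (percentile 0.0). The CAR/PXR list was at 0.09 (percentile 96.4) and -0.13 (percentile 0.4), with Cyp2b10 at 1.35 and -0.41 and Cyp2b9 at 1.75 and -0.12. The NRF2 list was at -0.08 (percentile 7.0) and 0.05 (percentile 93.0), and the PPARα list at -0.01 (percentile 36.4) and 0.04 (percentile 90.6). Heat shock genes (16) were at -0.32 (percentile 0.0) and -0.04 (percentile 31.1). The metallothionein list was at -0.30 (percentile 0.3) and 0.00 (percentile 57.6), although Mt2 was at 1.33 and -0.03. That first median, and the glucocorticoid list's first median of -0.16 (percentile 0.2), became 0.51 and 0.02 when the probe sets of each gene were averaged.

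In number, 297 genes were at least 2-fold higher and 314 lower on E+P than on P+P, and 458 higher and 459 lower on E+E than on P+E. In both, 26 were higher and 28 lower, against 28.5 and 29.3 for independent lists matched on signal (11.8 and 12.5 without matching), and 41 went opposite ways, against 59.4. The shared genes were no more than matched lists would share. Across genes the ratios were not correlated (r of -0.02, rho of -0.02, and r of 0.05 among the 3838 most abundant). The highest by both ratios were Clec2d (2.09 and 2.08), Usp49 (1.68 and 1.89), Zfp33b (1.78 and 1.69), Dhx58 (2.3 and 1.1), Smpd4 (2.15 and 1.26) and Meaf6 (1.79 and 1.53). With low signals set to the filter level, only Dhx58 of these stayed at least 2-fold in both, with its first ratio at 1.21. The first ratio was then 0.84 for Usp49, 0.59 for Zfp33b, 0.63 for Smpd4 and 0.78 for Meaf6. For Clec2d the second ratio was then less than 2-fold. The lowest were Lrrc46 (-1.67 and -2.47), Prune2 (-1.27 and -2.51), Cysrt1 (-2.29 and -1.48), Hspg2 (-0.84 and -2.85), Krt4 (-1.22 and -2.43) and Ppp1r3c (-0.84 and -2.73), which targets a phosphatase to glycogen. Set to the filter level in the same way, they were -0.97 and -1.38, -0.79 and -1.52, -1.71 and -1.48, -0.84 and -2.22, -0.31 and -2.43, and -0.84 and -1.63. For Cysrt1 the second value became 0.20 without probe sets that match several transcripts. All 6 of the highest and 4 of the lowest lay in the 3838 least abundant genes, and on a second probe set only 53.6% and 52.4% of genes at least 2-fold apart kept their sign, against 78.2% and 82.6% for the second exposure. A 75th percentile filter left 5 genes at least 2-fold the same way in both.

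**Figure D3:**
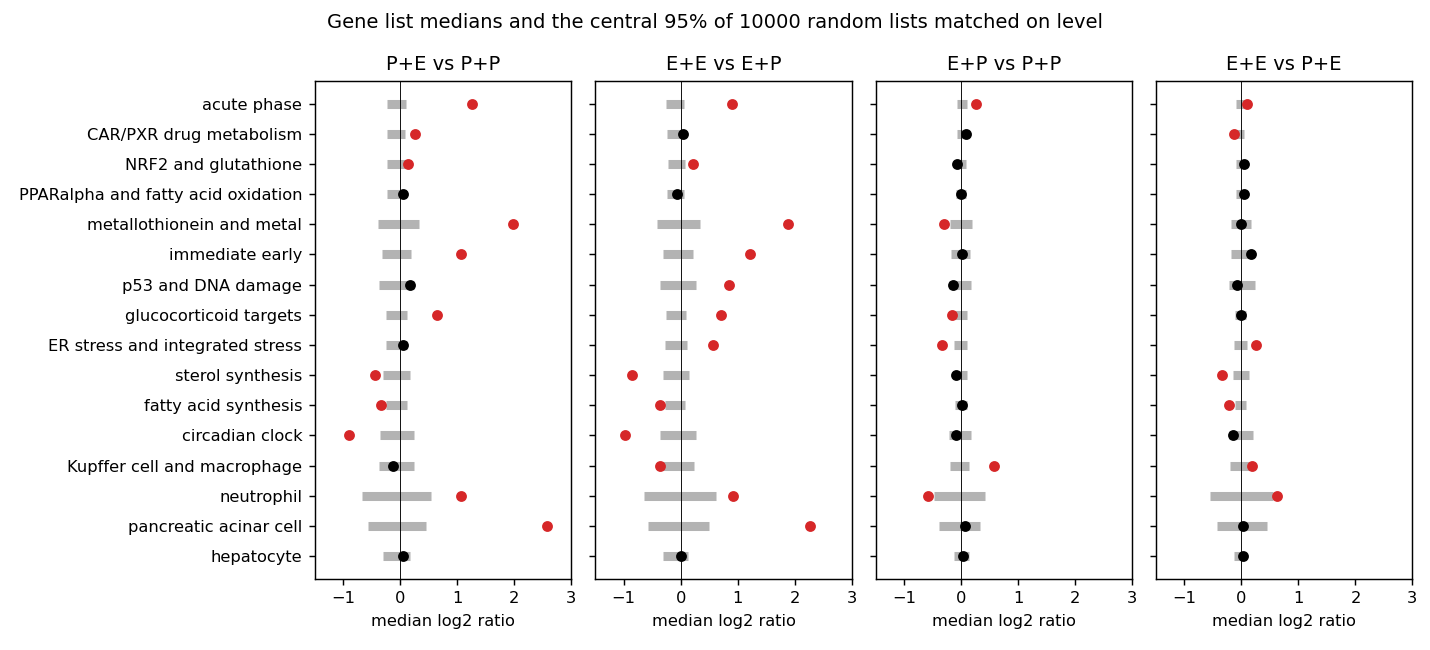
Median log2 ratio of 16 gene lists in the second-exposure ratios and the first-exposure ratios, with grey bars for the central 95% of 10000 random lists matched on signal. Red points lie outside the bars, such as acute phase genes at 1.26, 0.90, 0.27 and 0.10, and black points inside.

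Whether the first exposure altered the response to the second was measured by the difference of the second-exposure ratios, where a negative value means a lower ratio in mice given ethylbenzene first. Over 1044 genes with a mean ratio of at least 1 in size, the median difference in the direction of the response was 0.05. The ratios were less than 2-fold apart for 718 of them, and at least 2-fold larger for 164 and smaller for 162 in mice given ethylbenzene first. Lcn2 (-1.77, or -1.55 with P+P at the filter level), Cyp2b10 (-1.76), Orm2 (-1.64) and Mt2 (-1.36) had smaller ratios in mice given ethylbenzene first. Their signals were higher on E+P than on P+P and differed by at most 0.47 on the log2 scale between the arrays after ethylbenzene, as for Mt2 with 72015 on P+E and 70439 on E+E. Both the ratio of E+P to P+P and the difference of ratios use the P+P array. That array stood apart in its control probe sets, and its part in these values was not separated. Pdk4 had a larger ratio (1.88), with signals of 3220 on P+E and 7895 on E+E, but its signals of 112 on P+P and 59 on E+P lay below the filter level, and they accounted for 0.60 of the difference.

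ER stress genes had 25 of 29 above 0 and a median difference of 0.44 (percentile 100). Creld2 (1.93) and Atf3 (1.81, or 0.76 with signals below the filter level set to it) lay above 0, and Phgdh (-3.76, or -3.02 so set) below, although its ratio on P+E against P+P turned from 1.97 to -0.01 when its probe sets were averaged. The ratios of this list in the second exposure were 0.04 (percentile 88.9) and 0.56 (percentile 100). Heat shock genes (0.33, percentile 99.9) and neutrophil markers (0.82, percentile 98.1) also lay above the random lists, the latter at percentiles 96.8 and 96.7 under the other scalings. The medians of their second-exposure ratios were -0.12 and -0.18 for heat shock genes and 1.06 and 0.91 for neutrophil markers. Neither median was larger in mice given ethylbenzene first. On E+P against P+P both lists lay below the random lists (-0.32 and -0.58). Sterol synthesis genes lay below, with 16 of 19 below 0 and a median of -0.37 (percentile 0.0), including Msmo1 (-1.33). The CAR/PXR list (-0.19, percentile 0.5) and Kupffer cell markers (-0.38, percentile 0.3) were below too, as were the female-predominant list (-0.86, percentile 0.0, with 12 of 13 below 0) and the periportal list (-0.27, percentile 0.3). So was the skeletal muscle list added after the data were seen (-0.92, percentile 1.1, 8 genes). By contrast, the acute phase list (-0.13, percentile 5.1), the NRF2 list (0.03, percentile 73.1) and the PPARα list (-0.04, percentile 38.5) lay within the random lists. At least 2-fold differences of ratios were counted for 1739 genes, a number that was 307 with the 75th percentile filter, and the 12 named for the largest differences (among them Acta1, Prmt6 and Phgdh) all lay among the 3838 least abundant genes.

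Both exposures were compared with none on E+E against P+P. Lcn2 was at least 501-fold, Saa2 157-fold and Cyp2b10 148-fold higher, and Cyp7a1 was 39.1-fold lower. The acute phase list had a median of 1.39 (percentile 100), the CAR/PXR list 0.13 (percentile 99.5), the NRF2 list 0.11 (percentile 98.9) and the PPARα list -0.02 (percentile 86.1). Sterol synthesis genes were at -0.90 and clock genes at -1.09 (percentile 0.0 each). At least 2-fold differences were counted for 789 higher and 798 lower genes, and this comparison shares its arrays with the others.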

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

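No test of an explanation is reported in this part, and setting low signals to the filter level was chosen after the results were seen. Among the named genes, 17 had 2 ratios of the same exposure that were at least 2-fold in opposite directions, and the difference was not tested. Named genes include the 6 highest and 6 lowest differences of ratios by rule, so opposite directions among them follow in part from that choice. Over all genes past the filter, 53 went opposite ways in the second exposure and 41 in the first. Independent lists matched on signal would give 122.1 and 59.4. The difference of ratios was -7.22 for Acta1, -3.76 for Phgdh, -3.72 for Cd164l2, -3.62 for Slc22a6, -3.42 for Sorbs3, -3.28 for Tmem94 and -2.20 for Tnni2, which came from the skeletal muscle list added after the data were seen. It was 5.04 for Prmt6, 3.56 for Urb1, 3.23 for Engase, 3.23 for Pdzd2, 3.20 for Pnldc1, 3.19 for Rbmxl2, 2.79 for S100a5, 2.55 for Ier3, 2.28 for Tet1 and 2.23 for Ngp. These values depend on the pseudocount for 16 of the 17 genes, which had a signal below the filter level on at least 1 array. With such signals set to that level, the difference was -4.54 for Acta1, -3.02 for Phgdh, 2.61 for Prmt6, 2.43 for Urb1 and 3.04 for Rbmxl2, and these and Ngp were the 6 genes still at least 2-fold in opposite directions. For Phgdh this did not hold when its probe sets were averaged, since its ratio on P+E against P+P then turned. The skeletal muscle list had a difference of -0.92 (percentile 1.1). Acta1, the skeletal muscle actin gene, had signals of 28.3 on P+P, 291 on E+P, 1808 on P+E and 14.9 on E+E.

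The ER stress and integrated stress list lay on opposite sides of the random lists in the first-exposure ratios (-0.33 and 0.26), 0.59 apart, and the difference was not tested. The neutrophil list did so as well (-0.58 and 0.63), 1.22 apart, and the difference was not tested.

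Probe sets without a single gene name were not used for the genes above, and they carried signal too. Of 3206 past the filter, 95 were at least 2-fold higher in both second-exposure ratios, 60 were at least 2-fold lower in both, and 32 went opposite ways.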

How the results depend on the processing

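The E+P array in place of P+P as control was added after the data were seen, and under it the counts of P+E against P+P were 729 higher and 719 lower, and its 4 primary list medians kept their side. For E+E against P+P it is the comparison with E+P itself, where the counts were 796 and 777 and the CAR/PXR list median was 0.04 and no longer apart. The alternative for values already on a log scale was not run, since the values were linear. No paired analysis was possible because each group was 1 pool of different mice. The common 75th percentile scaling moved the median ratio of P+E against P+P to -0.11 from -0.07. Counts below are higher then lower. With the pseudocount at the 50th percentile they were 492 and 436 (P+E against P+P), 515 and 432 (E+E against E+P), 93 and 117 (E+P against P+P), 176 and 188 (E+E against P+E) and 463 lower (E+E against P+P), with 918 differences of ratios, 11 genes the same way in both first-exposure ratios, and 10 and 5 in opposite ways in the second-exposure and first-exposure ratios. With it at the 10th percentile, 86 and 63 went opposite ways. A larger pseudocount shrinks ratios by construction. With no low-level filter they were 1855 and 1765, 1875 and 1771, 1199 and 1313, 1491 and 1556, and 1826 and 1833, with 4676 differences of ratios, 930 and 369 genes the same way in both second-exposure and both first-exposure ratios, 350 and 361 in opposite ways, and a second-exposure correlation of 0.29. With the filter at the 75th percentile they were 355 and 264, 380 and 290, 38 and 34, 45 and 50, and 380 and 299, with 307 differences of ratios, 5 genes the same way in both first-exposure ratios, 0 in opposite ways in either exposure and a correlation of 0.77. The filter sets how many genes near background are counted. With the mean of all probe sets of a gene, 186 were lower on E+P than on P+P, 299 higher and 288 lower on E+E than on P+E, 32 were the same way in both first-exposure ratios, and 33 went opposite ways in the second-exposure ratios. The NRF2 list median on P+E against P+P was then 0.07 and within the random lists. The CAR/PXR list median on E+E against E+P was 0.13 as deposited and 0.09 at a common 75th percentile, both above the random lists, and the cause was not tested.

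Directions turned as follows, and the cause was not tested. On E+P against P+P, the mean of all probe sets gave 0.02 for glucocorticoid targets and 0.51 for the metallothionein list, and leaving out probe sets that match several transcripts gave -0.17 for Mt1. The mean of all probe sets gave -0.01 for Phgdh and 0.15 for Tet1 on P+E against P+P. Without probe sets that match several transcripts, Cysrt1 was at 0.20 on E+E against P+E and Tnni2 at -0.94 on E+P against P+P. Of 1598 alternative values of the list medians, 1513 kept their direction and side, 34 were no longer apart, 49 were newly apart and 2 turned. Of 1786 alternative ratios of named genes, 1727 kept their direction and side of the 2-fold rule, 51 ended below it, 3 passed it and 5 turned. Low signal over background limits the ratios of genes of low level.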

Other observations

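The tests of array scaling and of the P+P array, the skeletal muscle genes and the choice of these 3 patterns came after the results were seen. Genes expressed more in the liver of one sex than the other differed between arrays. The male-predominant list (13 genes) had medians of -0.68 on P+E against P+P and -0.72 on E+E against E+P (percentile 0.0 each), with Hsd3b5, a steroid dehydrogenase gene, at -3.10 and -2.28, while Elovl3 of this list was at 1.91 and 1.85. It was also at -0.37 on E+P against P+P (percentile 0.0) and at -0.14 on E+E against P+E (percentile 2.7). The female-predominant list (13 genes) was at 0.59 (percentile 99.9), -0.36 (percentile 4.2), 0.41 (percentile 99.9) and -0.12 (percentile 19.2) in the same order, and its difference of ratios was -0.86 (percentile 0.0). Pericentral genes (17), expressed near the central vein, had medians of -0.41 (percentile 0.3) and -0.57 (percentile 0.0) in the second exposure and 0.12 (percentile 94.7) and -0.07 (percentile 21.4) in the first, with Slc1a2 at -1.01 and -1.27. Periportal genes (16) had 0.02 (percentile 84.1), -0.09 (percentile 55.1), 0.11 (percentile 96.6, but 98.5 under both other scalings) and -0.06 (percentile 18.9), and a difference of ratios of -0.27 (percentile 0.3). Interferon response genes (23) had 0.22 (percentile 98.3), 0.25 (percentile 98.5), 0.15 (percentile 97.4) and 0.21 (percentile 97.7), the first 2 of which were at percentiles 97.0 and 96.1 as deposited. The histone deacetylase and DNA methylation list (21) had -0.06 (percentile 54.8), -0.09 (percentile 38.2), -0.07 (percentile 31.8) and -0.03 (percentile 36.4).

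Among cell type markers, in the same order of ratios, hepatocyte genes (10) had medians of 0.04 (percentile 85.1), -0.00 (percentile 85.5), 0.03 (percentile 57.2) and 0.03 (percentile 88.7), but as deposited both second-exposure medians (0.27 and 0.28) and that on E+E against P+E (0.14) were above the random lists. Kupffer cell markers in the second exposure were at -0.13 (percentile 35.6) and -0.37 (percentile 2.1). Sinusoidal endothelial markers (12) had -0.17 (percentile 26.6), -0.39 (percentile 2.2), 0.03 (percentile 68.5) and -0.18 (percentile 5.6), with Lyve1 higher (1.56 and 2.01). Stellate cell and fibroblast markers (14) had -0.31 (percentile 5.9), -0.06 (percentile 51.7), 0.06 (percentile 79.7) and 0.20 (percentile 98, but within the random lists under both other scalings). B cell (4 genes: 0.19, 0.03, 0.07 and 0.10), cholangiocyte (3: 0.62, 0.33, -0.02 and 0.44), mesothelium (3: -0.18, 0.33, -0.65 and -0.45) and erythroid markers (3: -0.85, -0.47, 0.45 and 0.09) lay within the random lists, apart from the first erythroid value under the other scalings. Monocyte (0.61, 1.07, -0.20 and 0.26), T and NK cell (-1.10, -0.46, -0.56 and 0.08) and adipocyte markers (1.38, 2.01, -0.83 and -0.19) had 2 genes each and no percentile. In the second exposure heat shock genes were at -0.12 (percentile 36.9) and -0.18 (percentile 19.3). In the first exposure the remaining medians were -0.09 (percentile 26.1) and 0.22 (percentile 93.0) for AHR targets, 0.02 (percentile 65.7) and 0.17 (percentile 95.2) for immediate early genes, -0.14 (percentile 10.5) and -0.07 (percentile 26.6) for p53 genes, -0.03 (percentile 46.1) and -0.09 (percentile 25.1) for cell cycle genes, -0.10 (percentile 3.2) and -0.10 (percentile 4.8) for bile acid genes, -0.09 (percentile 24.1) and -0.15 (percentile 11) for clock genes, -0.11 (percentile 19.2) and 0.15 (percentile 91.3) for NF-kB genes, and 0.07 (percentile 70.9) and 0.03 (percentile 55.7) for acinar markers. Of 15 skeletal muscle genes, 14 were above 0 on P+E against P+P (median 1.17) and 14 below 0 on E+E against P+E (median -1.0). Only 8 of the 15 passed the filter, and these had medians of 0.84 (percentile 99.8), -0.06 (percentile 42.4), 0.64 (percentile 99.6) and -0.48 (percentile 3.9, within the random lists), and a difference of ratios of -0.92 (percentile 1.1).

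Acinar markers were higher on both ethylbenzene-second arrays, and their lowest percentile over both ratios and 3 scalings was 100. The random lists were rescaled along with the markers, and the pattern was picked for being apart. The percentile therefore shows only that the call held under each scaling, and it does not test scaling as a cause. Pancreatic tissue carried into the specimens was asked about with a second acinar list, 1 gene of which is also in the first. In it 31.2% of the genes (5 of 16) were at least 2-fold higher in both ratios, short of the 75% that carry-over asked for. The bound set before these values were seen counted under 50% against carry-over, and it was met. It was set aside after the value was seen, because 8 of the 16 genes lay below the low-level filter and 4 of the 8 past it were higher in both. That filter uses the mean of all 4 arrays, so a gene low on the PBS-second arrays passes it only where it is high after ethylbenzene. The count past the filter thus favours the outcome, and carry-over stays open only with the bound set aside. A response of liver cells limited to acinar genes stays open too, since 1 of 7 endocrine genes was higher in both but 0 of the 7 passed the filter, so it and carry-over cannot be told apart. Markers on P+E and E+E were close in level (median size of their ratio 0.12, largest 0.38), and pool size and second exposure coincide.

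Clock output genes were lower on both ethylbenzene-second arrays, and the highest percentile of the clock list over both ratios and 3 scalings was 0.0. For the same reasons as above, this shows only that the call held under each scaling. A difference in the time of day of killing could account for the lower clock output genes. The 5 clock genes of the opposite phase had medians of 0.69 and 0.76, above the 0.5 that this explanation asked for. All 5 also belong to the clock list, and 1 lay below the filter, while of the other 4 2 were at least 2-fold higher in both ratios (Arntl and Nfil3) and 1 was below 0 in both. The times of killing were not given in the sources used here, and an effect of ethylbenzene on the clock stays open, as untested.

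Acute phase and macrophage genes leaned higher 7 days after the first exposure. The lowest percentile of both lists over 3 scalings was 100 on E+P against P+P. Here too the random lists were rescaled with the genes, so scaling as a cause was not tested by it. The RNA of the P+P array, with its high 18S signal, is not excluded. E+E against P+E leaves that array out, but the medians there were smaller (0.10 and 0.19, against 0.27 and 0.57). The lists were also picked, out of 37, for being apart in that ratio, so its percentiles of at least 99.8 (acute phase) and 98.5 (macrophage) decide nothing. A lasting effect of the first exposure and differences between the few pooled animals stay open, as untested.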
